A study of Homo sapiens with 13 samples.

How the data were processed

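Gene expression was measured in 13 tumours of the human melanoma line A375, 1 tumour per mouse, in 4 groups named in the labels by their mitochondrial DNA (mtDNA): WT (n = 3), ATP6 (n = 3), ND1 (n = 3) and CO1 (n = 4). Per the labels' protocols, RNA was extracted from frozen tumour tissue with a column kit and made into libraries with a 3' tag kit that reads the ends of polyadenylated transcripts, so the position of a read says nothing about the rest of the transcript and counts need no correction for gene length. Per the submitters' processing notes, Trim Galore 0.6.0 and HISAT2 were used, with the genome build GRCh38. The counting program, its strand setting, its handling of reads with several alignments and any removal of mouse reads are not given in the sources used here. The deposited table holds raw read counts per Ensembl gene, which are whole numbers with a different total in each library. Reads without molecular identifiers are not independent molecules, so intervals from counts cover counting error alone.

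Each of the 58735 gene identifiers in the table was found in GENCODE release 29, which gave chromosomes and GRCh38 coordinates, and symbols came from the same annotation and a symbol table. Reads shared between near-identical genes limit some values. The 4 copies of the nuclear 45S ribosomal RNA gene had nearly equal counts in each library and together held between 9.60% and 12.3% of the counts. CTAG1A and CTAG1B are near-identical copies on the X chromosome, and their counts cannot be assigned to either with certainty. Nuclear pseudogenes of mtDNA can take or give reads to the mtDNA-encoded genes, and genes that overlap an antisense partner are uncertain because the strand setting is unknown.

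Totals ran from 4151140 to 6270835 counts, with a median of 5453034. The filterByExpr function of edgeR (version 4.0.16 in R 4.3.3), with a minimum count of 10 and the genotype as group, kept 14984 genes. Libraries were scaled by the trimmed mean of M-values (TMM), with factors between 0.960 and 1.05. Levels are given as CPM, the deposited counts scaled to a common library total with these factors. All 13 libraries entered 1 quasi-likelihood fit in edgeR with a mean per genotype, and the 6 differences between genotypes were tested from it, with Benjamini-Hochberg adjusted p below 0.05 as the threshold. A log2 fold change is followed by its standard error (SE), which is its size divided by the square root of the F statistic, and a mean CPM by its standard deviation (SD).

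The design, the alternatives, 37 gene lists and the rule for named genes were chosen before the data were examined. The rule took, for each mutant against WT, the 12 largest rises and the 12 largest falls among genes past the threshold with a mean count of at least 10 and no overlap between the groups, and 5 each way for pairs of mutants. It left out antisense, readthrough, pseudogene and clone-named genes. It added up to 4 members of each list with the smallest p and all 13 mtDNA-encoded mRNAs. An X-linked non-coding RNA and some other genes that the rule names are not reported here. Counts of MT-ATP6, MT-ND1 and MT-CO1 do not check the genotype labels, since a mutated gene can be transcribed at its usual level.

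Lists with at least 5 tested members (33 of the 37) were tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, and p was adjusted over the lists within a comparison. Camera was repeated with a correlation estimated from the data, and the rotation test fry was run as an alternative. The estimated correlation ended each list call: in ATP6, ND1 and CO1 against WT, 2, 7 and 9 lists, and in ATP6 against ND1, ATP6 against CO1 and ND1 against CO1, 4, 10 and 13 lists passed with the preset correlation and 0 with the estimated correlation. The share of counts from mtDNA was compared between groups with exact two-sided permutation tests, which cannot give a p below 0.1 for 3 against 3 libraries or below 0.0571 for 3 against 4.

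The tests were checked on simulated counts drawn with the means, library sizes and spread of these libraries, over 14984 genes. Each set held 100 genes changed by a log2 fold of 2 and 100 changed by 1, up or down. In the simulated CO1 against WT comparison, edgeR recovered 68.6% of genes changed by a log2 fold of 2 and 23.4% of those changed by 1, with 5.6 false calls per set. In the simulated ATP6 against WT comparison the shares were 66% and 19.8%. Camera found the changed list in 5 of 5 simulated sets, with the preset and with the estimated correlation. These sets drew each gene independently and raised all 30 genes of the list by a log2 fold of 1. They therefore do not test false calls in lists whose genes vary together, or the detection of smaller shifts.

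Alternatives were scaling by relative log expression (RLE) or by the upper quartile, leaving out mtDNA-encoded genes, no filter on low counts, a mean of at least 50 counts, a fit of the 2 genotypes compared, the replicate number as a block, DESeq2 1.42.0, limma-voom and leaving out each library in turn. A fit of protein-coding genes only was added after the data had been seen. No pair of libraries within a group was a duplicate: the chi-square per degree of freedom between replicates ran from 9.88 to 24.0. Replicates are separate mice, while the labels do not say how many independent cell populations of each genotype were injected. Figures were drawn with matplotlib 3.10.9.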

Results

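Subcutaneous tumours were grown in the flanks of NSG mice, which lack functional lymphocytes, from 10000 injected A375 cells and taken at a diameter of 20 to 25 mm. The cells carried WT mtDNA or mtDNA labelled ATP6, ND1 or CO1. MT-ATP6 encodes a subunit of ATP synthase, MT-ND1 a subunit of respiratory complex I and MT-CO1 the catalytic subunit of cytochrome c oxidase (complex IV). The comparisons ask how the tumour transcriptome differs between each mutant genotype and WT, and between the mutant genotypes. Library totals ran from 4151140 to 6270835 counts and between 20394 and 22940 genes had at least 1 count. Totals averaged 5744000 in CO1 and 5095000 in WT, and genes with a count 22660 ± 288 (SD, n = 4) and 21370 ± 907 (SD, n = 3), each with an exact two-sided permutation p of 0.0571, the smallest possible (0.171 adjusted over the 3 comparisons with WT). On the 500 most variable genes, the CO1 tumours lay between 18.59 and 32.01 on the first principal component (38.1% of variance), and the highest of the other 9 tumours lay at 0.97.

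**Figure D1:**
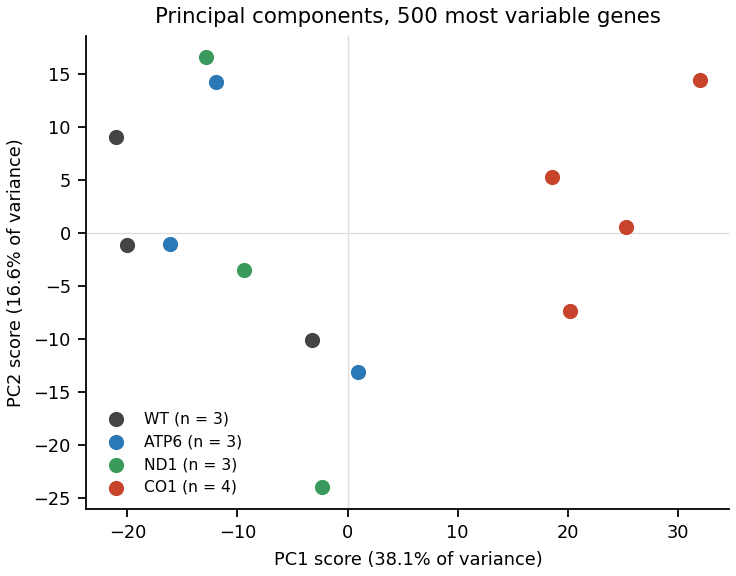
Scores of the 13 tumours on the first (horizontal, 38.1% of variance) and second (vertical, 16.6%) principal components of log2 CPM of the 500 most variable genes, with 1 point per tumour coloured by genotype. The 4 CO1 tumours lie at 18.59 or above on the horizontal axis, and all other tumours lie at 0.97 or below.

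In CO1 against WT tumours, SEMA6D, a transmembrane semaphorin, rose by a log2 fold change of 4.64 (SE 0.50), from 1.19 ± 0.275 CPM in WT (SD, n = 3) to 29.99 ± 5.04 CPM in CO1 (SD, n = 4). SCD, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, fell by 1.37 on the log2 scale (SE 0.19), from 113 ± 30.4 to 43.8 ± 5.19 CPM. CA9, a carbonic anhydrase induced by hypoxia, went from 19.1 ± 13.5 to 0.448 ± 0.331 CPM, a log2 fold change of -5.36 (SE 0.93). In edgeR's test, 96 genes rose and 91 fell among the 14984 tested, and 149 of these 187 changed more than 2-fold. The WT and CO1 values of all 187 did not overlap, while 16.3% of all tested genes had no overlap, against 5.71% by chance. Of the 90 genes that rose on the autosomes and chromosome X, 22 (24.4%) lay on chromosome 2, which holds 6.78% of the 14930 genes tested there. The count fell to 10 without WT replicate 2 or WT replicate 3, 14 without CO1 replicate 3, 74 without CO1 replicate 1, 95 without CO1 replicate 4 and 113 without ND1 replicate 1. It was 741 with DESeq2, 88 with limma-voom and 1374 with no filter on low counts.

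The largest rise in CO1 against WT was that of PWWP3B, with a log2 fold change of 6.45 (SE 1.18). ROBO2, a receptor for axon guidance signals, followed at 5.96 (SE 0.91), and ALDH1A2, an enzyme of retinoic acid synthesis, at 5.54 (SE 1.02). The DNA replication factor RADX rose by 4.88, the acetylcholine receptor subunit gene CHRNA1 by 4.42, ISLR by 4.41, CYTL1 by 4.36 and NEFM, a neurofilament subunit, by 4.26 to 542 ± 362 CPM. RGS5, a pericyte marker, rose by 4.20, the receptor gene LRP1B by 4.04 and MXRA8 by 3.96. The adjusted p of these 11 genes and SEMA6D lay between 0.00306 (SEMA6D) and 0.0481 (CHRNA1). SEMA6D (ENSG00000137872) lies on chromosome 15 from 47184101 to 47774223 in GRCh38. The calls of SEMA6D and SCD (ENSG00000099194, chromosome 10, 100347124 to 100364834) held in all 23 alternatives. Among the genes named in this comparison, the calls that held least often were those of RPS4X (7 of 23), CHRNA1 (8 of 22), PFKFB4 and DNAJB1 (9 of 23 each), COX17 (10 of 23), MXRA8 and CPT1A (11 of 23 each).

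The genes that fell in CO1 included 3 cancer-testis antigen genes. CTAG2 (ENSG00000126890, chromosome X, 154651972 to 154653579 in GRCh38) had 29.7 ± 7.32 CPM in WT, and the 4 CO1 libraries together held 2 of its counts, a ratio of 0.00293 (95% counting interval 0.000354 to 0.0107). CTAG1A and CTAG1B, near-identical copies that encode NY-ESO-1, fell from 61.7 ± 10.7 and 59.1 ± 12.6 CPM to 0.267 ± 0.182 and 0.266 ± 0.353 CPM. The CTAG2 call was lost without WT replicate 2, WT replicate 3 or CO1 replicate 3 and with limma-voom (adjusted p up to 0.28). Other falls were those of AJAP1 (log2 fold change -7.71, SE 1.47), SIRPB1 (-4.85), CDH13 (-4.73), the cytosolic DNA sensor AIM2 (-4.62), SMOC1 (-3.89), FAM133A (-3.38) and FRMD3 (-3.31), with adjusted p between 0.0146 (FAM133A) and 0.0290 (AIM2). Of the 18 tested members of the cancer-testis list, these 3 CTAG genes fell and the other 15 did not pass, and PRAME, the next by p, had a log2 fold change of 0.46 (adjusted p = 0.181). The list passed camera as lower (adjusted p = 0.00451; adjusted p = 0.204 with an estimated correlation), with a median log2 fold change of -0.23 and a mean of -1.39.

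**Figure D2:**
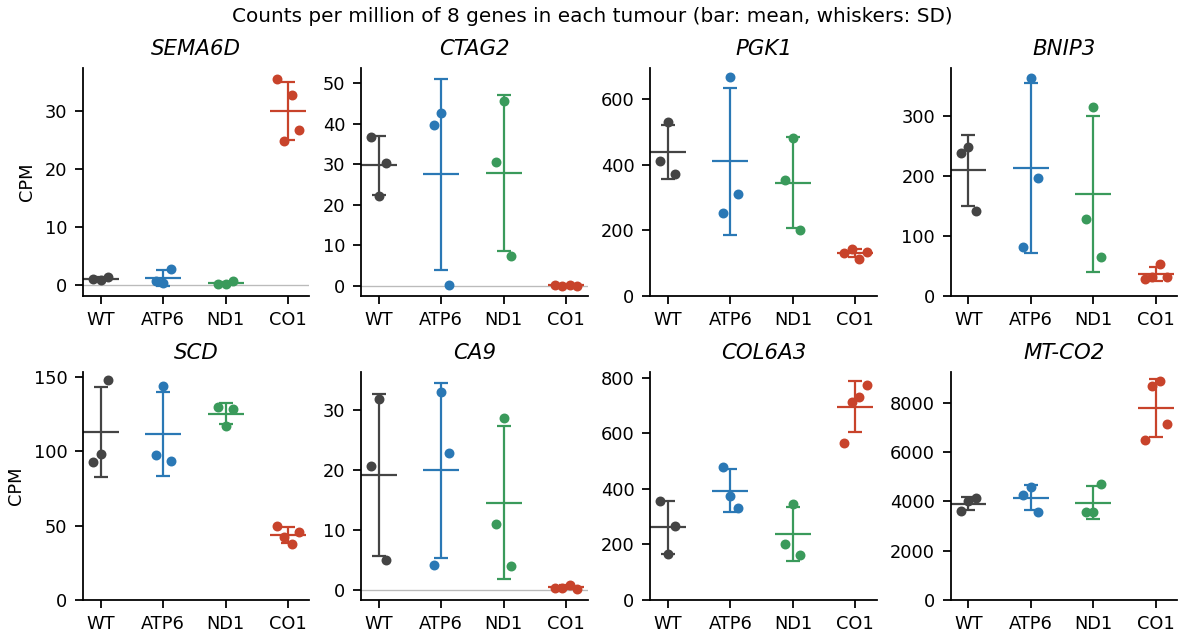
CPM (vertical axes, from 0) of 8 genes in each of the 13 tumours, grouped by genotype, with a bar at the mean and whiskers of 1 SD. SEMA6D, COL6A3 and MT-CO2 are higher in CO1 than in WT (log2 fold changes 4.64, 1.42 and 1.00), and CTAG2, PGK1, BNIP3, SCD and CA9 are lower (-8.05, -1.75, -2.54, -1.37 and -5.36).

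Hypoxia and glycolysis genes were lower in CO1 than in WT. Of 29 tested targets of hypoxia-inducible factor, 24 had negative values, 5 fell, none rose, and 13 fell when adjusted over the list alone. The mitophagy receptor gene BNIP3 fell by 2.54 on the log2 scale (SE 0.51), from 210 ± 59.3 to 36.3 ± 11.3 CPM, and the oxidoreductase gene ERO1A fell by 1.24 (SE 0.19). Of 23 glycolysis genes, 20 had negative values, 3 fell, and 11 fell when adjusted over the list alone. The lists overlap in SLC2A1, SLC2A3, PDK1, PFKFB3 and PFKFB4 and together hold 47 distinct tested genes. SLC2A1 and PFKFB4 count among the falls of both. The glycolytic enzyme gene PGK1 fell by 1.75 (SE 0.31), the glucose transporter gene SLC2A1 by 2.14 (SE 0.45) and PFKFB4, a regulator of glycolytic flux, by 2.30 (SE 0.52). The BNIP3 call held in 15 of 23 alternatives and that of SLC2A1 in 13 of 23. Each was lost when any WT or CO1 library was left out. LDHA, which makes lactate, had a log2 fold change of -1.06 (adjusted p = 0.0620). The median log2 fold change was -1.01 for the hypoxia list (camera adjusted p = 7.1e-11; adjusted p = 0.426 with an estimated correlation) and -0.60 for glycolysis (camera adjusted p = 9.89e-10; adjusted p = 0.332 with an estimated correlation).

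Most mtDNA-encoded mRNAs were higher in CO1 than in WT. Of 13 tested, 4 rose, 0 fell, and 8 rose when adjusted over the list alone. MT-CO2, which encodes a complex IV subunit, rose from 3904 ± 277 to 7786 ± 1170 CPM (log2 fold change 1.00, SE 0.15). The complex I subunit genes MT-ND6, MT-ND4 and MT-ND5 rose by 0.78 (SE 0.15), 0.66 (SE 0.12) and 0.61 (SE 0.12). MT-CO1 itself had 1594 ± 197 CPM in WT and 1850 ± 228 CPM in CO1 (log2 fold change 0.22, SE 0.14, adjusted p = 0.441), and MT-CYB and MT-ATP6 had values of -0.31 and -0.14 that did not pass. The median log2 fold change was 0.48 (camera adjusted p = 5.16e-07; adjusted p = 0.339 with an estimated correlation). Nuclear genes of the respiratory complexes did not pass as lists: the medians were 0.09 over 36 complex I genes, 0.01 over 13 of complexes II and III and 0.12 over 12 of complex IV. COX17, a copper chaperone for complex IV assembly, fell by 0.65 (SE 0.14), and SUCLG2, a subunit of the TCA cycle enzyme succinyl-CoA ligase, by 0.79 (SE 0.15).

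The cholesterol synthesis, heat shock and proliferation lists also passed camera as lower in CO1, and none of the 3 did with an estimated correlation. Of 21 cholesterol synthesis genes, 15 had negative values and the median was -0.49 (camera adjusted p = 0.00444; adjusted p = 0.512 with an estimated correlation). That list no longer passed without WT replicate 3 (adjusted p = 0.0753; 8.25e-05 to 0.512 over its alternatives). DNAJB1, a heat shock co-chaperone, fell by 0.86 (SE 0.19), and 20 of the 23 heat shock and unfolded protein genes had negative values (median -0.43, camera adjusted p = 3.4e-07; adjusted p = 0.204 with an estimated correlation). All but 1 of 30 proliferation genes had negative values and none was called (median -0.57, camera adjusted p = 9.04e-07; adjusted p = 0.663 with an estimated correlation). The mean log2 level of that list, relative to its mean over the 13 tumours, was -0.715 and -0.915 in CO1 replicates 1 and 3 but 0.008 and 0.015 in CO1 replicates 2 and 4, and -0.520 in WT replicate 2. GDF15, a cytokine induced by mitochondrial and integrated stress, rose by 3.69 (SE 0.73), from 15.9 ± 11.2 to 207 ± 149 CPM, while 38 of 39 integrated stress response genes were not called. CPT1A, the gateway enzyme of mitochondrial fatty acid oxidation, rose by 1.02 (SE 0.22).

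Interferon-stimulated genes were higher as a list in CO1: 32 of 36 had positive values, and 17 rose and 2 fell when adjusted over the list alone. BST2, a restriction factor, rose by 2.28 (SE 0.49) and ISG20, an exonuclease, fell by 1.92 (SE 0.41). The median was 0.89 (camera adjusted p = 1.91e-08; adjusted p = 0.516 with an estimated correlation). The level of the list was 1.212 and 0.945 in CO1 replicates 1 and 3 but 0.005 and 0.206 in CO1 replicates 2 and 4, against 0.083 in WT replicate 2. Fibroblast and pericyte markers were higher too: COL3A1 (2.09, SE 0.47), COL6A3 (1.42, SE 0.28), PDGFRB (1.36, SE 0.29) and RGS5 rose among 13 tested, of which 12 had positive values (median 1.36, camera adjusted p = 6.55e-08; adjusted p = 0.204 with an estimated correlation). The level of these markers lay between 0.669 and 1.047 in the 4 CO1 tumours and reached at most 0.313 in the other 9, while the level of the glycolysis list lay between -0.469 and -0.400 in CO1 and at -0.275 or above in the others. Reads of mouse origin were not separated here. Of 4 tested endothelial markers and 2 myeloid markers none was called, with medians of 0.92 and -1.79. The mesenchymal and invasion list (26 of 28 genes not called, camera adjusted p = 0.194) and the list of dedifferentiated melanoma (17 of 20 not called, camera adjusted p = 0.479) did not pass. Among their members, ADAM12 rose by 1.76 (SE 0.28), while NT5E fell by 1.90 (SE 0.35), LOXL2 by 1.51 (SE 0.30) and the urokinase receptor gene PLAUR by 1.46 (SE 0.27). NFKB1 fell by 1.34 (SE 0.29), and the ribosomal protein genes RPL8 and RPS4X fell by 0.85 (SE 0.14) and 0.84 (SE 0.19), while the other 76 ribosomal protein genes tested were not called.

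**Figure D3:**
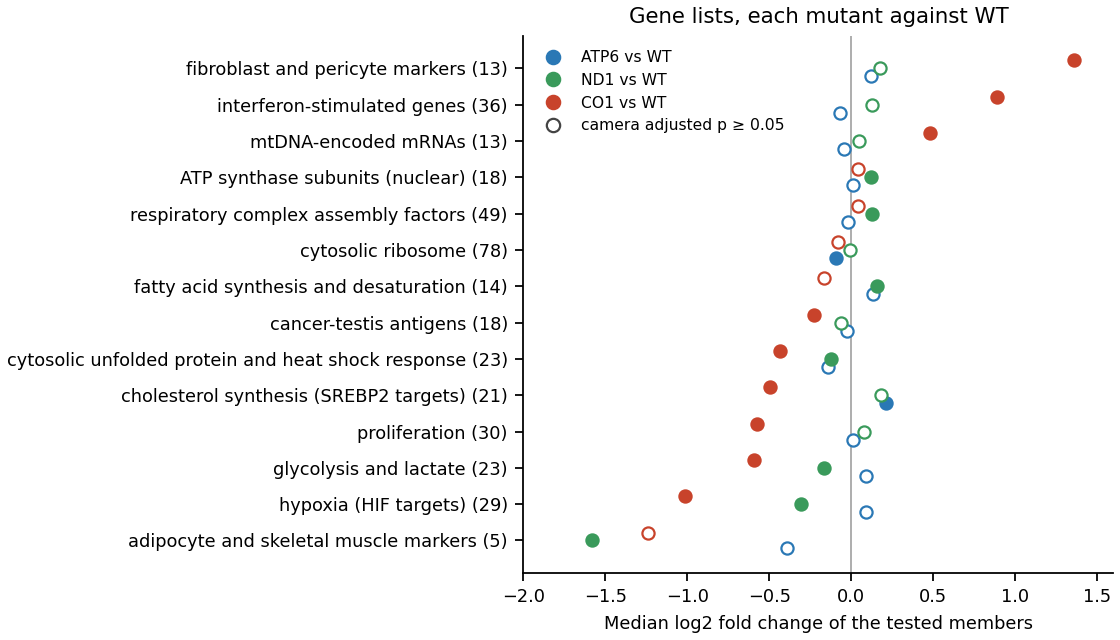
Median log2 fold change (horizontal axis) of the tested members of 14 gene lists, each mutant against WT, with the number of tested members in brackets, filled where the list passed camera with the preset correlation and open where it did not. The CO1 points run from -1.24 for adipocyte and muscle markers, which did not pass, to 1.36 for fibroblast and pericyte markers, and none passed with an estimated correlation.

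In ATP6 against WT, no gene passed in edgeR: 0 genes rose and 0 fell, with 431 genes below an unadjusted p of 0.05. DESeq2 called 3 genes and limma-voom called 0. The 24 false calls that DESeq2 gave per simulated set arose beside planted changes. They are no rate for unchanged groups and do not judge these 3 calls. The edgeR fit called 1 gene without WT replicate 1 and 104 with no filter on low counts. Ribosomal protein genes were slightly lower in ATP6: 67 of 78 had negative values and the median log2 fold change was -0.09 (camera adjusted p = 0.00146; adjusted p = 0.993 with an estimated correlation). RPS20 had -0.30 (SE 0.13) and RPL7 -0.32 (SE 0.15), each with an adjusted p of 1. Cholesterol synthesis genes were higher, with a median of 0.21 over 21 genes, 16 of them positive (camera adjusted p = 0.0117; adjusted p = 0.993 with an estimated correlation). INSIG1, a sterol-regulated membrane protein gene, had 31.5 ± 4.62 CPM in ATP6 and 20.0 ± 1.09 CPM in WT (log2 fold change 0.66, SE 0.28). MT-ATP6 had a log2 fold change of -0.13 (SE 0.16). The ribosome call was lost without WT replicate 2 or ATP6 replicate 1, and the cholesterol call without WT replicate 1 or 2 or ATP6 replicate 1 or 2. Without WT replicate 3, 8 lists passed, and without WT replicate 2, 1 list.

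In ND1 against WT, 0 genes passed in edgeR, with 459 below an unadjusted p of 0.05, and DESeq2 and limma-voom each called 0. With no filter on low counts, edgeR called 146. Hypoxia genes were lower, with a median of -0.31 and 22 of 29 negative (camera adjusted p = 0.0410; adjusted p = 0.857 with an estimated correlation), and glycolysis genes had a median of -0.17 with 19 of 23 negative. SLC2A1 had 42.0 ± 14.9 CPM in ND1 and 68.9 ± 23.2 CPM in WT (log2 fold change -0.72, SE 0.47). ATP synthase genes (median 0.12), assembly factors of the respiratory complexes (0.13) and fatty acid synthesis genes (0.16) were higher, and heat shock and unfolded protein genes lower (-0.12). For these and glycolysis, the camera adjusted p was 0.0473, and the adjusted p was 0.857 with an estimated correlation. Skeletal muscle and adipocyte markers were lower (median -1.58 over 5 genes, camera adjusted p = 0.0410; adjusted p = 0.857 with an estimated correlation), and the myosin gene MYH1 had 2.38 ± 0.949 CPM in ND1 and 18.8 ± 29.1 CPM in WT. WT replicate 3 held 52.48 CPM of MYH1, against 2.813 and 1.208 CPM in the other WT tumours, and the muscle call was lost without that library or without ND1 replicate 1. Whether these reads came from the melanoma cells or from mouse tissue was not tested. The number of lists was 1 without ND1 replicate 1 or ATP6 replicate 3, 2 without CO1 replicate 2, 3 without WT replicate 1 or ND1 replicate 3, 4 without WT replicate 2 or ATP6 replicate 1 or 2, 12 without WT replicate 3 and 17 without ND1 replicate 2. MT-ND1 had a log2 fold change of 0.17 (SE 0.20, adjusted p = 1).

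Between ATP6 and ND1, 0 genes passed in edgeR, with 519 below an unadjusted p of 0.05, while DESeq2 called 2 and limma-voom 0. The edgeR fit called 1 gene without ATP6 replicate 3 and 195 with no filter on low counts. Glycolysis genes (median 0.25, camera adjusted p = 0.00224) and hypoxia genes (0.39, camera adjusted p = 0.00411) were higher in ATP6, and assembly factors (-0.14, camera adjusted p = 0.0128) and ribosomal protein genes (-0.11, camera adjusted p = 0.00224) lower. The adjusted p of all 4 was 0.966 with an estimated correlation. PFKFB4 had 41.1 ± 33.3 CPM in ATP6 and 17.5 ± 4.20 CPM in ND1, and HILPDA, a lipid droplet gene induced by hypoxia, 229 ± 218 and 88.9 ± 47.6 CPM. The glycolysis and hypoxia calls were lost without ATP6 replicate 2, ND1 replicate 1 or ND1 replicate 3, the assembly factor call without ATP6 replicate 1 or either of those ND1 libraries, and the ribosome call without ATP6 replicate 1 or ND1 replicate 2. Without ND1 replicate 1 or ND1 replicate 3, 1 list passed.

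In ATP6 against CO1 tumours, CTAG2 (27.5 ± 23.7 CPM in ATP6), CTAG1A, CTAG1B and CA9 were higher in ATP6, with log2 fold changes of 7.94, 7.49, 7.50 and 5.43. CTAG2 had 2 counts in CO1, a ratio of 324 with a counting interval of 89.1 to 2690, but ATP6 replicate 3 held 0.2319 CPM of it, against 39.62 and 42.67 CPM in the other ATP6 tumours. The CTAG2 call was lost without ATP6 replicate 2 or any of the 4 CO1 tumours, and with the replicate block or limma-voom (adjusted p up to 0.476). ALDH1A2 (-5.42, SE 1.02), the progenitor and endothelial marker CD34 (-5.04, SE 0.75), SEMA6D (-4.56, SE 0.50), the sorting receptor gene SORL1 (-4.46, SE 0.86) and RAB7B (-2.85, SE 0.55) were lower in ATP6. PGK1 (1.65), PFKFB4 (2.70), ERO1A (1.28) and SCD (1.35) were higher, and MT-CO2 (-0.91), MT-ND4 (-0.88), COL3A1 (-2.66), CPT1A (-1.23) and the immediate early gene EGR1 (-1.31) lower. The calls of ERO1A and SCD held in 21 of 23 alternatives, whereas those of PFKFB4 (5 of 23), ALDH1A2 and RAB7B (6 of 22 each), SORL1 (7 of 22), EGR1 (8 of 23) and PGK1 (9 of 23) were lost in most. In all, 22 genes were higher and 21 lower at an edgeR adjusted p below the threshold, against 3 and 9 with limma-voom and 150 and 200 with DESeq2, and 10 lists passed camera, of which hypoxia (median 1.12; adjusted p = 0.238 with an estimated correlation), glycolysis (0.65; adjusted p = 0.238 with an estimated correlation) and interferon-stimulated genes (-0.90; adjusted p = 0.389 with an estimated correlation) had the smallest p. Cholesterol synthesis (0.52), heat shock (0.26) and cancer-testis genes (median 0.16, mean 1.08) were also higher in ATP6, and mtDNA-encoded mRNAs (-0.46) and fibroblast markers (-1.02) lower (adjusted p = 0.238 with an estimated correlation for each). Proliferation (0.50; adjusted p = 0.404 with an estimated correlation) and fatty acid synthesis genes (0.37; adjusted p = 0.295 with an estimated correlation) were higher. The cancer-testis call was lost without ATP6 replicate 1, CO1 replicate 1 or CO1 replicate 4. The gene count was 1 without ATP6 replicate 2, 13 without ATP6 replicate 3, 14 without CO1 replicate 3, 17 without CO1 replicate 1, 20 without CO1 replicate 2, 25 without ND1 replicate 1 and 86 without ATP6 replicate 1.

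ND1 and CO1 tumours differed in 68 genes, 25 higher and 43 lower in ND1, against 510 genes with DESeq2 and 33 with limma-voom. SEMA6D had 0.367 ± 0.316 CPM in ND1 (log2 fold change -6.26, SE 0.57, edgeR adjusted p = 0.000439). ALDH1A2 had 1 count in the ND1 libraries and STOX2 had 3, ratios of 0.00479 (counting interval 0.000121 to 0.0269) and 0.0215 (0.0044 to 0.0638) against CO1. LRP1B (-5.08) and RADX (-4.99) were also lower, and CTAG2 (7.96), CTAG1A (7.54), CTAG1B (7.43) and CA9 (4.96) higher in ND1. The CTAG2 call was lost without ND1 replicate 1 or 2 or CO1 replicate 1, 2 or 3, and with the replicate block or limma-voom (adjusted p up to 0.328). ND1 replicate 3 held 7.308 CPM of CTAG2. SCD (1.52), the chaperone regulator gene BAG3 (1.16) and SUCLG2 (0.99) were higher, and MT-CO2 (-0.98), BST2 (-2.48), COL6A3 (-1.56) and EGR1 (-1.23) lower. The call of EGR1 held in 6 of 23 alternatives and that of RADX in 11 of 22. Of 13 lists past camera, proliferation had 30 of 30 positive values (median 0.67; adjusted p = 0.447 with an estimated correlation) and hypoxia a median of 0.87 (adjusted p = 0.465 with an estimated correlation). The mitochondrial ribosome list was higher in ND1, with 58 of 74 positive values (median 0.20; adjusted p = 0.591 with an estimated correlation), and no member was called. Cholesterol synthesis (0.62), glycolysis (0.39), heat shock (0.32), fatty acid synthesis (0.31), cancer-testis (median 0.09, mean 1.36) and ribosomal protein genes (0.08) were also higher in ND1. Fibroblast markers (-1.19), interferon-stimulated (-0.76), mtDNA-encoded (-0.41) and integrated stress response genes (-0.27) were lower. With an estimated correlation, the adjusted p of these 10 lists lay between 0.344 for cholesterol synthesis and 0.698 for ribosomal protein genes. The integrated stress response call was lost without ND1 replicate 1 or 3 or CO1 replicate 2 or 4, the ribosome call without ND1 replicate 2 or CO1 replicate 3 and the cancer-testis call without CO1 replicate 1. The gene count was 1 without ND1 replicate 1, 2 without ND1 replicate 2, 4 without CO1 replicate 3, 17 without CO1 replicate 1 and 25 without ND1 replicate 3.

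Transcripts of mtDNA, mRNA and ribosomal RNA together, made up 15.0% ± 1.74 of the counts in CO1 tumours (SD, n = 4) and 11.2% ± 1.04 in WT (SD, n = 3), a difference of 3.81 percentage points (exact two-sided permutation p = 0.0571, the smallest possible; 0.171 adjusted over the 3 comparisons). The shares were 12.3% ± 1.24 in ATP6 (exact permutation p = 0.4) and 11.7% ± 0.529 in ND1 (exact permutation p = 0.5), where 0.1 is the smallest possible. With mRNAs alone, the share was 6.6% ± 0.326 in CO1 and 4.97% ± 0.338 in WT (exact permutation p = 0.0571).

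The fold changes of the mutants against WT were correlated across the 14984 genes, which are not independent replicates. Pearson's r was 0.423 for ATP6 and ND1, 0.417 for ATP6 and CO1 and 0.422 for ND1 and CO1. Unchanged groups simulated against the same WT libraries gave means of 0.501, 0.538 and 0.543. The covariance was 0.1059, 0.1606 and 0.1695, against 0.1250, 0.1247 and 0.1244 in the simulations, differences of -0.0191, 0.0359 and 0.0450. The simulations drew each gene independently, and the correlation of ATP6 and ND1, where no gene was called, lay below their whole range (0.472 to 0.526). They are therefore no calibrated value for unchanged groups, and the differences from them are not read as a shared effect. Without WT replicates 1, 2 and 3 in turn, the covariance was 0.3412, 0.2035 and 0.2095 for ATP6 and ND1, 0.4571, 0.2728 and 0.2431 for ATP6 and CO1 and 0.4935, 0.2803 and 0.2582 for ND1 and CO1. With a mean of at least 50 counts it was 0.0353, 0.0655 and 0.0693, and no simulated value was computed for these settings. With 3 WT libraries, a split that keeps 2 in each part was not possible. No call was made in ATP6 or ND1, so the overlap of calls was 0 with 0 expected.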

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

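The counts of genes and lists in other splits of the libraries, the test of 20 Mb bins and the tests of the hypoxia and glycolysis levels in CO1 against the other 9 tumours are tests chosen only after the result was seen.

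Genes whose change against WT differed between mutants numbered 43 for ATP6 and CO1 and 68 for ND1 and CO1, by the test of the difference itself. Among the 98 values per CO1 tumour that were examined, 8 had 1 tumour far from the other 3, and chance gives about 1 in 20. CO1 replicate 1 stood apart with 1.8 CPM of AIM2 (0 to 0.16 in the others) and 18.9 CPM of STOX2 (3.84 to 5.96). Its mean log2 levels were 0.085 for TCA cycle genes (-0.063 to -0.041) and 0.169 for mesenchymal and invasion genes (-0.364 to -0.281). Its 0.539 CPM of CTAG1A (0.160 to 0.186) was also flagged. These CTAG1A values rest on a few reads that cannot be told from those of CTAG1B, so they do not set the tumour apart. The rate of 1 in 20 is not known to hold for counts so near 0. CO1 replicate 2 had 20.5 CPM of PWWP3B (39.5 to 42.9), CO1 replicate 3 a level of -0.037 for nuclear complex I genes (0.057 to 0.07) and CO1 replicate 4 had 16.9 CPM of PDGFRB (34.3 to 35.9).

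Fold changes between CO1 and WT shifted by chromosome: the median over genes with a mean count of at least 50 was 0.30 on chromosome 2, 0.29 on chromosome 22 and -0.28 on chromosome 8. Of the 90 genes that rose on the autosomes and chromosome X, 24.4% lay on chromosome 2, which holds 6.78% of the genes tested there, and of the 91 that fell 14.3% lay on chromosome 8 (3.57% of tested genes) and 13.2% on chromosome X (3.88%), which holds the CTAG genes. A trend with GC content and expression does not account for them, since 96.9% of the spread of chromosome medians was left after correction, and 1 of the 35 splits of the 7 libraries gave as large a spread, the real split (0.127, highest other 0.109). Differences in nuclear gene dosage between CO1 and WT cells may underlie the shifts, with weak support from a test that in part restates them (chromosome explained 65.8% of the variance of 20 Mb bin medians, against at most 26.8% in 1000 shufflings), and not all shifts belong to CO1: chromosome 2 had medians of -0.30 in ATP6 against CO1 and -0.26 in ND1 against CO1, while chromosome 8 had -0.28 in ATP6 against WT, -0.12 in ND1 against WT and 0.05 in ATP6 against CO1, with levels of 0.227 and 0.280 in WT replicates 1 and 3 and -0.014 in WT replicate 2. On chromosome 22, the level of ATP6 replicate 3 (0.162) lay above that of CO1 replicate 2 (0.063). The CO1 tumours also differed among themselves: chromosome 12 had -0.313 in CO1 replicate 1 and -0.030 to 0.002 in the others. Chromosome 13 had 0.060 in CO1 replicate 1 and -0.295 in CO1 replicate 2. ND1 replicate 3 had -0.288, -0.270 and -0.318 on chromosomes 15, 16 and X. Whether the shifts found in CO1 go with its mtDNA or with another property of these cells stays open. All CO1 tumours carry that mtDNA, and the labels do not say whether they share a cell population.

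The lower level of hypoxia and glycolysis genes in CO1 kept 94.1% of its median (-0.87 before, -0.82 after) when the chromosome medians were subtracted. These medians lay between -0.284 and 0.300, so the subtraction could not have removed a fall of that size. Shifts on the genes' own chromosomes are thus too small to account for it, while effects of such shifts on genes elsewhere were not tested. A chance spread between tumours stays open: in the 4 CO1 tumours against the other 9, the exact two-sided permutation p adjusted over 33 lists was 0.0231 for the glycolysis list and 0.0554 for the hypoxia list, and the hypoxia levels of ATP6 replicate 1 (-0.587) and ND1 replicate 3 (-0.570) lay below those of CO1 replicates 1 (-0.235) and 3 (-0.504). An effect of the CO1 mtDNA on these genes, or of another property of the injected cells, remains possible as an untested hypothesis. Vascularisation and growth time of the tumours were not analysed here.

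The higher level of fibroblast and pericyte markers in CO1 kept 102% of its median with the chromosome medians subtracted. The subtraction could not have removed it, since the chromosome medians lay between -0.284 and 0.300. Shifts of that size on the genes' own chromosomes are too small to account for a median of 1.36. Effects of such shifts on genes elsewhere were not tested. RNA of mouse stromal cells aligned to human genes may contribute: COL1A1, COL1A2, DCN and LUM, abundant in fibroblasts and themselves members of the list, had a median log2 fold change of 1.44 in a fit without a low-count filter, against 1.36 for the list. COL1A2 had 124 ± 58.2 CPM in WT and 455 ± 94.9 CPM in CO1 (log2 fold change 1.90, edgeR adjusted p = 0.0505) and COL1A1 had 492 ± 163 and 703 ± 174 CPM (0.53, adjusted p = 0.358). Expression of these genes by the melanoma cells themselves stays open, since reads of mouse origin were not separated here.

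In CO1 against WT, 1 of the 35 splits of the 7 libraries into 4 and 3 gave as many genes as the real split, the real split itself (187, highest other 0). The same held for ATP6 and CO1 (1 of 35, real count 43, highest other 1) and for ND1 and CO1 (1 of 35, real count 68, highest other 2). Each share is the smallest that 35 splits can give and was not adjusted over the 6 comparisons. These 3 comparisons share the 4 CO1 tumours and are not separate support. A chance split of the libraries is thus less likely for these counts of genes but not excluded. In lists past camera the real split did not stand out. At least the 9 lists of CO1 against WT came from 21 of 35 splits (highest other 17). For ATP6 and CO1, 14 of 35 gave at least 10 (highest other 13), and for ND1 and CO1, 4 of 35 gave at least 13 (highest other 15). The 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real gene count was 0, the highest other 0 and the number of splits with as many 10 for ATP6 and WT, ND1 and WT, and ATP6 and ND1. For lists, the real counts were 2, 7 and 4, the highest others 17, 16 and 11, and 9, 6 and 9 splits had as many.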

How the results depend on the processing

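The fit of protein-coding genes was the alternative chosen after seeing the data. No gene called in the main analysis changed sign in any alternative, and 2 of the 52 called and named genes in CO1 against WT, SEMA6D and SCD, held in all 23. The cause of each change below was not tested, except that the estimated prior degrees of freedom were 5.06 with the low-count filter and infinite without it, so that each gene then takes the fitted trend of the spread.

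With no low-count filter, the counts of genes were 104 (ATP6 against WT), 146 (ND1 against WT), 1374 (CO1 against WT), 195 (ATP6 and ND1), 1075 (ATP6 and CO1) and 1185 (ND1 and CO1). DESeq2 gave 3, 0, 741, 2, 350 and 510 in that order, and limma-voom 0, 0, 88, 0, 12 and 33. The 2 genotypes fitted alone gave 16 genes higher and 29 lower for ATP6 and CO1. DESeq2 called all 187 genes of CO1 against WT and limma-voom 85 of them. For ATP6 and CO1, leaving out mtDNA-encoded genes gave 27 and protein-coding genes alone 26. Leaving out 1 library at a time gave 0 to 1, 0 to 0, 10 to 229, 0 to 1, 1 to 86 and 1 to 81 genes.

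Numbers of lists were 0 in all 6 comparisons with an estimated correlation, and 0, 0, 4, 0, 2 and 0 with fry. The 4 of CO1 against WT were mtDNA-encoded mRNAs, heat shock, cancer-testis and fibroblast genes. Leaving out 1 library gave 1 to 8, 1 to 17, 9 to 12, 1 to 6, 10 to 15 and 12 to 15 lists. ATP6 against WT had 3 lists when the 2 genotypes were fitted alone.

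The replicate numbers did not pair the libraries: 4 of 18 same-number pairs had deviations correlated above 0.1 (range -0.345 to 0.348), and 4 of 12 libraries correlated best with their own number. With the replicate number as a block, the counts of genes were 0, 0, 78 (55 higher and 23 lower, 63 shared with the main calls), 0, 16 (3 and 13) and 43 (5 and 38). Those of lists were 4, 7, 11, 4, 11 and 13. Number 4 occurs only in CO1, so its block term fits CO1 replicate 4 exactly and takes that library out of the comparisons. Leaving out CO1 replicate 4 alone, without a block, gave 95 genes in CO1 against WT (64 higher and 31 lower). The effect of the block itself is therefore not separated.

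The mtDNA share in ATP6 was 1.06 percentage points above WT, and -0.121 with mRNAs alone. The share differences ran from 0.378 to 1.64 (ATP6), 0.0517 to 1.05 (ND1) and 3.01 to 4.39 (CO1) without single libraries. The correlations of the mutant effects were 0.398, 0.372 and 0.366 with a mean of at least 50 counts, and 0.534 to 0.657, 0.463 to 0.638 and 0.474 to 0.644 without 1 WT library.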

Other observations

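The comparison of CO1 with all other tumours below was chosen only after the results were seen.

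Mean log2 levels of the 33 tested lists were compared between the 4 CO1 tumours and the other 9 by exact two-sided permutation over 715 splits, which keeps the correlation between genes. After adjustment over the 33 lists, 8 passed, 4 higher and 4 lower. Higher in CO1 were mtDNA-encoded mRNAs (difference 0.42), integrated stress response genes (0.29), interferon-stimulated genes (0.86) and fibroblast and pericyte markers (1.32), with adjusted p of 0.0231, 0.0231, 0.0264 and 0.0231 in the exact test. Lower were glycolysis (-0.64), cholesterol synthesis (-0.47), heat shock (-0.37) and cancer-testis genes (-0.98), with exact adjusted p of 0.0231, 0.0264, 0.0264 and 0.0346. The cancer-testis level is a mean that few genes can carry. In CO1 against WT its median log2 fold change was -0.23, the mean was -1.39 and 15 of 18 members were not called. The level in ATP6 replicate 3 (-0.537) lay below those in CO1 replicates 2 (-0.534) and 3 (-0.503). Levels also overlapped for interferon-stimulated genes (lowest CO1 0.005, highest other 0.083). They did so for cholesterol synthesis (highest CO1 -0.171, lowest other -0.183) and heat shock genes (highest CO1 -0.008, lowest other -0.039). Against WT alone, the integrated stress response list did not pass camera (adjusted p = 0.416), with a median log2 fold change of 0.09. For mtDNA-encoded mRNAs, glycolysis, integrated stress response and fibroblast markers the unadjusted p was 0.0028, the smallest that these splits give. The hypoxia list had an exact adjusted p of 0.0554.

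Other genes called in CO1 against WT, chosen after their values were seen, included the neural crest and neuronal genes TUBB2B, which rose from 28.4 ± 11.6 to 150 ± 41.5 CPM (log2 fold change 2.40), and SEMA3A (1.25), the homeobox gene HOXD13 (2.86), the secreted factor genes BMP7 (2.14) and IGFBP2 (1.92), the elastin gene ELN (3.21) and the oxygen-binding globin gene CYGB (2.53). Those lower in CO1 included the integrin gene ITGB8, which fell from 59.5 ± 31.1 to 9.14 ± 2.98 CPM (-2.70), the mitochondrial calcium uniporter gene MCU (-1.22), the transcription factor gene SOX5 (-1.20), the tumour suppressor gene RB1 (-0.95) and the survival factor gene MCL1 (-0.78). Their adjusted p in edgeR lay between 0.00748 (TUBB2B) and 0.0391 (IGFBP2). Chromosome medians were not subtracted from these fold changes, and reads of mouse origin were not separated.

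Single tumours differed from their group in ways that no genotype comparison covers. CTAG2 was at 0.2319 CPM in ATP6 replicate 3 and at 7.308 CPM in ND1 replicate 3, against 22.15 to 45.58 CPM in the other non-CO1 tumours. MITF, the master regulator of pigment cell genes, was at 135.3 CPM in CO1 replicate 1 and between 7.048 and 20.87 CPM in all other tumours. The myosin genes MYH1 and MYH2 were at 52.48 and 43.02 CPM in WT replicate 3 and 29.6 and 18.88 CPM in ATP6 replicate 1, and at most 4.967 CPM in the other 11 tumours. Reads of mouse origin were not separated, so the myosin reads need not come from the melanoma cells.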
